A study of Mus musculus with 27 samples.

How the data were processed

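Total RNA of NIH/3T3 cells, an established mouse embryonic fibroblast line, was measured on 27 Affymetrix mouse U74v2 arrays, 1 array per sample. Per the labels' protocols, cultures received a 2 h pulse of 15 µM forskolin, an activator of adenylyl cyclase that raises cyclic AMP, in serum-free medium, and were then rinsed and kept in serum-free medium. Flasks were harvested at 0 h, right after the pulse, and every 6 h up to 48 h, in 3 experiments that the labels call biological replicates. The 9 time points were the groups, with 3 arrays each, and the experiment number was the replicate number. Cultures without the pulse were not analysed here, and neither were the other cells and the tissue that the series title names.

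The deposited values are linear probe set intensities. The algorithm that made them is not given in the sources used here. Their mean after leaving out 2% of the probe sets at each end lay between 500.28 and 500.35 on every array, so each array had been scaled to a common target before deposit. The array medians ranged from 166.8 to 200.7. Signal detection calls were not used here, so a low intensity could not be told from background, and the number of arrays limits the precision. No 2 arrays held identical values. The table held 12488 probe sets, of which 66 were Affymetrix controls, and 1 empty cell, in a control.

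Values were taken as log2(intensity + 12.1), the pseudocount being the 10th percentile of all values, so that fold changes are on that scale and understate changes of dim probe sets. The array medians spread over 0.25 on the log2 scale, above the limit of 0.2 set in advance, and the log2 values were therefore quantile normalized. Probe sets below the 40th percentile of mean log2 value and the controls were left out, which kept 7453 probe sets. Of all probe sets, 10855 had 1 gene symbol in the platform annotation, 396 had several and were not named, and 1193 without control status were not listed there. Through their gene identifiers 10839 of the 10855 matched the mouse RefSeq table (assembly GRCm38.p6), and 0 symbols changed. Each gene was represented by its brightest probe set, which gave 5643 genes.

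Tests used limma 3.58.1 in R 4.3.3 with an intensity trend in eBayes and Benjamini-Hochberg adjustment, at an adjusted p below 0.05. All arrays shared one fit of the 9 time means for the contrasts and for the F test over time. The rhythm was tested as cosine and sine terms of a 24 h period beside a linear trend, on the 24 arrays from 6 h to 48 h, and the same fit gave the trend, in log2 units per day. A further fit gave the 2 cycles separate cosine and sine terms. Of 32 gene lists, 29 had 5 or more measured genes and were tested with camera at a preset correlation of 0.01, or with Fisher's exact test, one-sided, for rhythm calls. Camera was also run with a correlation estimated from the data. For the comparisons over time this was done without the experiment as a block, so differences between experiments enter the estimate.

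Genes were named by a rule. For each contrast and the trend these were the 10 largest rises and 10 largest falls with an adjusted p below 0.05 and 1 sign in all 3 experiments. For the rhythm the rule allowed the 20 largest amplitudes among calls whose mean profiles of the 2 cycles correlated positively. Each list added up to 4 called members with the largest change, or the member with the smallest p, and the core clock list added every measured member. The lists, the rule, most of the tests and most of the other settings were fixed before the data were examined. The list tests at 48 h against 24 h were not among the planned tests.

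The experiment numbers were checked for pairing. Deviations from the time point means correlated between arrays of the same experiment in every pair, with r across probe sets from 0.426 to 0.642 in experiment 1, 0.349 to 0.599 in experiment 2 and 0.135 to 0.482 in experiment 3. The numbers therefore paired the samples, and counts with the experiment as a block are given beside the probe set counts that they moved by more than 1.5 times. The first principal component held 28.7% of the variance and set experiment 1 apart from the other 2.

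The code was tested on simulated data with the real means, spread and experiment effects and a set of changed probe sets among 7453, of which 67 changed by 0.5, 67 by 1 and 66 by 2. For 6 h against 0 h, 52.2% of changes of 1 on the log2 scale and 92.4% of changes of 2 were recovered without the block, against 85.1% and 97.0% with it. For the 24 h rhythm, 74.6% of amplitudes of 0.5 and 92.5% of amplitudes of 1 were recovered without the block. The simulation drew independent noise, with no arrays out of place.

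Alternatives changed the scaling, the pseudocount, the filter, the variance model, the array weights, the block, the period, the trend term, the time points and the replicates. The 3′ to 5′ ratios of the control probe sets served as a check of RNA quality: the actin ratio ran from 1.11 to 1.73 and the Gapdh ratio from 0.703 to 0.916 over the arrays.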

Results

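The 27 arrays followed NIH/3T3 fibroblasts for 48 h after a 2 h forskolin pulse, with 3 experiments at each of 9 time points. The series asked which transcripts of these fibroblasts follow a circadian course. All values are log2 intensities after quantile normalization, changes are given ± SE with n = 3 arrays per time point, and adjusted p-values come from limma. Where the block is not named, the SE and adjusted p of a change over time come from the fit without it. That fit leaves the differences between experiments in the spread, so these SEs do not measure the spread of the paired changes. A gene said not to pass may pass with the block. The 0 h arrays were taken at the end of the pulse, so a comparison with 0 h shows change since that moment and not change from untreated cells.

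Over the whole course 544 of 7453 probe sets varied between time points, of which 404, or 74.3%, had their highest or lowest mean at 0 h. Their highest mean fell at 0 h for 169 probe sets, at 6 h for 118 and at 48 h for 77. With the experiment as a block the count was 1968, and without experiment 3 it was 31 and without experiment 2 it was 113. Each later time point differed from 0 h in between 453 probe sets, at 6 h, and 616, at 12 h, against 1246 and 1522 at these times with the block. At 48 h, 349 were higher and 241 lower than at 0 h, against 802 and 683 with the block.

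**Figure D1:**
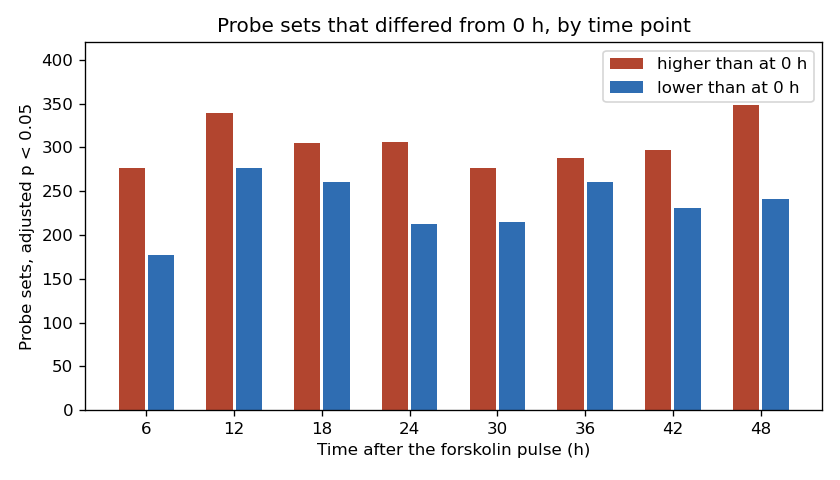
Bars give the number of probe sets with an adjusted p below 0.05 against 0 h in the fit without the block (y axis) at each time point in hours (x axis), split by direction. Higher probe sets outnumbered lower ones at every time point, from 276 against 177 at 6 h to 349 against 241 at 48 h.

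The first comparison asked what changed in the 6 h after the pulse. The largest fall was that of Vdr, the vitamin D receptor, by −4.30 ± 0.35 (adjusted p = 4.64e-08). Fosl1, an AP-1 subunit, fell by 2.97 ± 0.67, Srxn1, the sulfiredoxin gene, by 2.88 ± 0.23, Dgat1, which catalyses the last step of triglyceride synthesis, by 2.64 ± 0.19, and Acta2, smooth muscle actin, by 2.61 ± 0.46. Hsph1, Abcf2, Ramp3, Pdpn and Slc25a25 fell by between 2.43 and 2.11. The largest rises were those of Kank3 at 2.61 ± 0.48, Txnip at 2.38 ± 0.36, Six5 at 2.37 ± 0.61, Traf5 at 2.15 ± 0.23 and Stard10 at 2.10 ± 0.32. Tyro3, a receptor tyrosine kinase, Ifi30, F3, which encodes tissue factor, Ifit2 and Tec rose by between 2.06 and 1.89. The 0 h means of Kank3, Six5, Tyro3, Tec and Ifit2 were 6.75, 6.72, 6.75, 6.60 and 5.25. They lay below 6.77, the lowest mean over all arrays that the filter kept, so the size of these rises is uncertain. A dimmer probe set of Txnip gave −0.07 ± 0.21. Without experiment 1 the change of Txnip was 1.70 and that of Fosl1 −2.15 (adjusted p = 0.171), and without experiment 2 that of Fosl1 was −3.64. In all, 276 probe sets rose and 177 fell, against 741 and 505 with the experiment as a block. Without experiment 3 the count was 110 and without experiment 2 it was 148.

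Of 25 measured cAMP and CREB targets, 9 fell at 6 h, 1 rose and 15 did not pass, and adjusted over the list alone 10 fell and 2 rose. Hk2, the hexokinase 2 gene, fell by 1.78 ± 0.48, Cebpd by 1.76 ± 0.19, and Nfil3 and the nuclear receptor gene Nr4a1 each by 1.58. Of 24 immediate early genes, 6 fell and 1 rose, with Fosl1 followed by Nr4a1, Dusp6 at −1.52 ± 0.44 and Dusp1 at −1.43 ± 0.42. The camera test placed both lists lower than other genes (adjusted p = 2.80e-05 and 0.0150). With an estimated correlation the adjusted p = 0.0542 and 0.308. The median change of the immediate early list differed between the experiments, with a mean of −0.36 ± 0.57 (SD, 3 experiments). Without experiment 1 the change was −1.05 for Hk2 (adjusted p = 0.152), −0.86 for Nr4a1 and −0.90 for Dusp6 (adjusted p = 0.283).

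Of 25 genes of the actin cytoskeleton and SRF targets, 6 fell at 6 h, 8 adjusted over the list alone and 12 with the block, among them Acta2, Myl9 at −1.14 ± 0.25, Actg2 at −1.13 ± 0.19 and Cnn2 at −1.03 ± 0.20. The camera test gave an adjusted p = 2.80e-05, and an adjusted p = 0.0505 with an estimated correlation. Of 35 genes of ribosome biogenesis and MYC targets, 3 fell over all genes tested, 11 adjusted over the list alone and 14 with the block, with Nop56 at −1.38 ± 0.24, Ddx21 at −1.18 ± 0.28 and Srm at −1.05 ± 0.30. This list had an adjusted p = 2.80e-05, and an adjusted p = 0.0733 with an estimated correlation. Of 19 heat shock genes, 17 had a negative change and 2 passed, against 4 with the block, namely Hsph1 and Bag3 at −1.55 ± 0.24. The heat shock list kept its call with an estimated correlation (adjusted p = 0.00658).

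Lipid genes went both ways at 6 h. Of 20 genes of fatty acid oxidation, 17 had a positive change and 5 rose, 6 adjusted over the list alone, with Angptl4, an inhibitor of lipoprotein lipase, at 1.60 ± 0.25, Acadm, the medium-chain acyl-CoA dehydrogenase, at 1.13 ± 0.21, Cpt1a, which brings fatty acids to the mitochondrion, at 0.82 ± 0.20 and Echs1 at 0.81 ± 0.24. The list was higher than other genes by camera, also with an estimated correlation (adjusted p = 0.00658). Of 18 genes of fatty acid synthesis and storage, 3 fell and 1 rose, against 5 and 2 with the block. Dgat1, Acsl4 at −1.55 ± 0.26 and Elovl5 at −0.55 ± 0.14 fell, and Plin2, a coat protein of lipid droplets, rose by 1.25 ± 0.18. That list had an adjusted p = 0.0326, and an adjusted p = 0.243 with an estimated correlation.

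Of 18 measured interferon response genes, 15 had a positive change and 4 rose at 6 h, namely Ifi30 at 1.98 ± 0.36, Ifit2 at 1.96 ± 0.48, Gbp2 at 1.81 ± 0.20 and Tap1 at 0.65 ± 0.18. This list kept its call with an estimated correlation (adjusted p = 0.00658). Of 31 genes of growth arrest, p53 and FoxO targets, 7 rose and 1 fell, against 11 and 3 with the block: Txnip, Bcl2l11 at 1.05 ± 0.16 and Sesn1 at 1.00 ± 0.16 rose and Gadd45b fell by 1.30 ± 0.29. Its adjusted p = 0.0461 became an adjusted p = 0.0733 with an estimated correlation. Of 25 genes of oxidative stress and NRF2, 3 fell, Srxn1, Gclc at −1.45 ± 0.33 and Txnrd1 at −1.40 ± 0.18, with an adjusted p = 0.0252. It became an adjusted p = 0.0582 with the block and an adjusted p = 0.0542 with an estimated correlation. Of the lists of other cell types, 1 of 9 muscle genes, Actc1 at −1.81 ± 0.37, and 1 of 8 neuron and glia genes, Thy1 at −1.38 ± 0.20, fell, and neither list was called.

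Of 35 genes of G2 and mitosis, none passed at 6 h, where Incenp had the smallest p at −0.53 ± 0.26 (adjusted p = 0.310). At 24 h, 6 fell and none rose, and 22 fell adjusted over the list alone and 29 with the block. Smc2, a condensin subunit, was among them, Cks2 fell by 1.45 ± 0.40, Ccnf by 1.19 ± 0.27 and Plk1, the polo-like kinase, by 1.04 ± 0.31. The median of the list was −0.02 at 6 h, −0.32 at 12 h, −1.38 at 18 h and −1.20 at 24 h. Of 32 genes of S phase and replication, 7 fell at 24 h, 15 adjusted over the list alone and 20 with the block, with Pcna, the polymerase clamp, at −1.58 ± 0.23, Rrm1 at −1.37 ± 0.21, Fen1 at −1.24 ± 0.36 and Pola1 at −1.10 ± 0.26. Camera gave both lists an adjusted p of 1.19e-13 and 3.21e-11. With an estimated correlation the adjusted p = 0.226 and 0.111, and that correlation was 0.592 in the first list. It came from the fit without the block, so differences between experiments enter it. Their part in it was not tested.

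**Figure D2:**
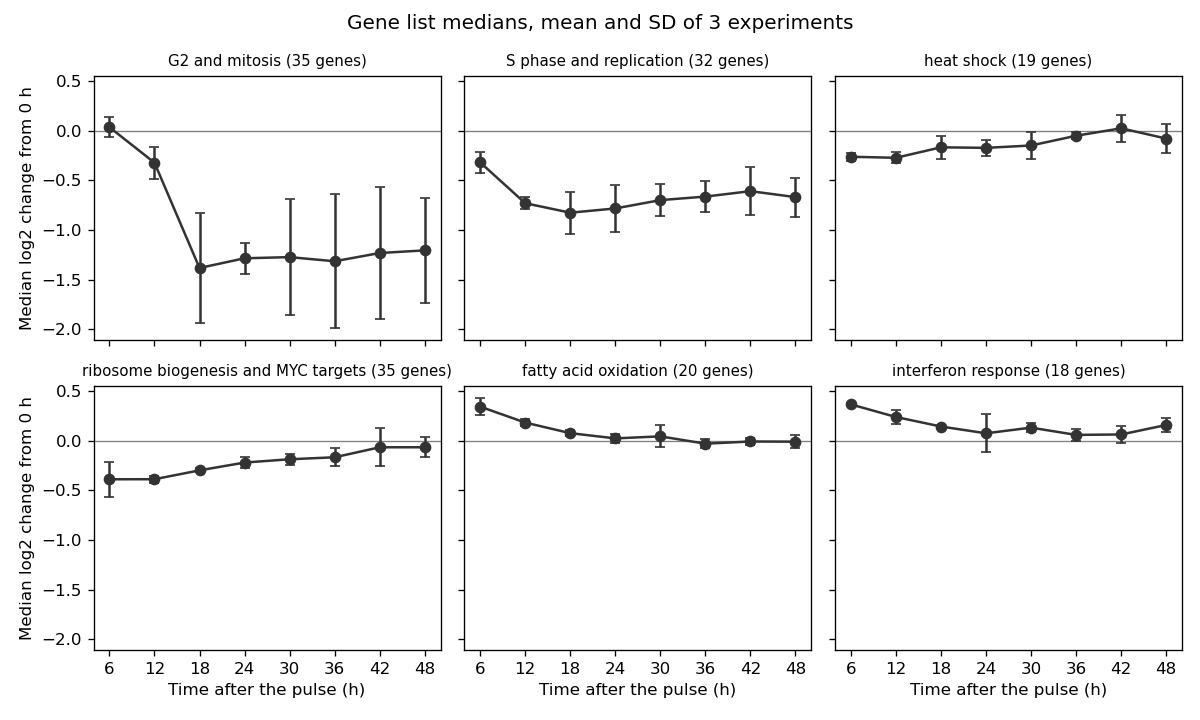
Each panel plots the median log2 change from 0 h (y axis) of 1 gene list against time in hours (x axis). Points are means of the medians of 3 experiments and bars their SD, and the mean for the G2 and mitosis list was 0.04 at 6 h and −1.38 at 18 h.

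The other changes from 0 h to 24 h were led by Vdr at −4.74 ± 0.35, Srxn1 at −3.13 ± 0.23, Fosl1 at −3.01 ± 0.67, Dgat1 at −2.82 ± 0.19 and Tnc, the matrix protein tenascin C, at −2.79 ± 0.27. Nav2, Acta2, Gadd45g, Ramp3 and Slc25a25 fell by between 2.68 and 2.35. Another probe set of Srxn1, at 0.15 ± 0.35, and one of Txnip, at −0.14 ± 0.21, had the opposite sign at 24 h and did not pass. Nbl1, an extracellular BMP antagonist, rose by 2.79 ± 0.34, Kank3 by 2.67 ± 0.48, Spsb1 by 2.33 ± 0.22, Apod by 2.32 ± 0.68 and Klf13 by 2.28 ± 0.45. Hivep2, Ifit2, Txnip, Ifi30 and Traf5 rose by between 2.19 and 2.01. The 0 h means of Kank3, Apod, Hivep2 and Ifit2, at 6.75, 6.71, 6.20 and 5.25, lay below 6.77, the lowest mean that the filter kept. So did the 24 h means of Nav2 and Gadd45g, at 6.70 and 6.55, and the size of these changes is uncertain. Fosl1 changed by −4.52, −0.98 and −3.52 in experiments 1 to 3, and its change was −2.25 without experiment 1 (adjusted p = 0.133) and −4.02 without experiment 2. Without experiment 1 the change was also 1.41 for Ifit2 (adjusted p = 0.0527) and for Txnip, −1.71 for Acta2 and 2.88 for Klf13. In all, 306 probe sets rose and 213 fell, against 790 and 597 with the block. Without experiment 3 the count was 126 and without experiment 2 it was 197.

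Of 46 extracellular matrix genes 9 rose and 6 fell at 24 h, against 15 and 9 with the block, and the list was not called (adjusted p = 0.4996). Lama4, a laminin chain, rose by 1.57 ± 0.18, while Tnc, Col11a1 at −1.40 ± 0.30 and Has2, a hyaluronan synthase, at −1.34 ± 0.27 fell. Of 25 cAMP and CREB targets, 8 fell and 1 rose, with Rgs2 at −2.29 ± 0.30 and Bdnf at −1.67 ± 0.31. Of 25 NRF2 genes, 4 fell, against 8 with the block, and of 28 proteasome genes 2 fell, against 14 with the block, Psma1 at −0.69 ± 0.21 and Psmd13 at −0.65 ± 0.15. Camera called 11 of the lists at 24 h, all lower, and none of the 11 with an estimated correlation, where the smallest adjusted p = 0.0712. With the block the ATF4 list (adjusted p = 0.0532, and 0.0307 with the block) and the ER chaperone list (adjusted p = 0.0615, and 0.0163 with the block) were called as well. Neither of them was called with an estimated correlation.

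Further tests asked whether the course repeated after a day. Between 24 h and 48 h 2 probe sets differed, Cryz at −0.74 ± 0.12 and Pafah1b3 at −0.65 ± 0.11, and 337 had an unadjusted p below 0.05. With the block 13 were higher and 29 lower. Neither passed with the scaling as deposited (adjusted p = 0.0709 for both), with each array centred on its median, with eBayes without the intensity trend, or without experiment 2 or 3, each of which gave 0 calls. Of 24 immediate early genes 21 had a positive change and none passed, with Atf3 at 1.25 ± 0.35 (adjusted p = 0.568). List tests were not planned for this comparison, and they were left out of the splits of the arrays and of most alternatives. Camera placed the immediate early list higher at 48 h (adjusted p = 3.81e-07), and the adjusted p = 0.171 with an estimated correlation. The lists of hypoxia, ER chaperones, heat shock, ribosome biogenesis and proteasome were also called higher and that of lysosome and autophagy lower, and none of them was called with an estimated correlation, where the smallest adjusted p = 0.171. No probe set passed the test of a 24 h rhythm in limma, with 247 at an unadjusted p below 0.05 where 372.7 are expected by chance. None passed with the block either, but 785 were at that level, more than the 372.7. Without the block the differences between experiments stay in the spread. No probe set passed the test of a rhythm that differed between the 2 cycles, with 300 at an unadjusted p below 0.05, also fewer than expected. With the block 65 passed, with 891 at that level, more than expected. Adjusted over the list alone and without the block, 7 of 35 genes of G2 and mitosis and 3 of 25 actin and SRF genes passed this test of the cycles, as did 1 gene each of glycolysis, growth arrest, cytokines and growth factors. The fit held only a linear trend beside the rhythm terms, so a change over time that is not linear can pass too. The G2 and mitosis median fell within the first cycle, so the calls of that list do not show a changed rhythm. At an unadjusted p below 0.05 there were 17 genes of G2 and mitosis, 8 of S phase and replication and 6 of 46 of extracellular matrix. The ATF4 and cytokine lists had 5 each, and the actin and SRF and growth arrest lists 4 each.

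Of the 13 measured core clock genes, none was called rhythmic, and adjusted over the list alone none passed without the block and 1, Rora, with it. Per3, a period gene, had an amplitude of 0.45 ± 0.14 with its peak at 21.1 h (adjusted p = 0.171 by limma, adjusted over the list alone). For amplitudes, here and below, the value after ± is the SE of the cosine term and not of the amplitude. Rora, a nuclear receptor that acts on the Arntl promoter, had 0.27 ± 0.09 with its peak at 18.6 h. Cry1, a repressor of the clock, had 0.24 ± 0.11, Nr1d2 0.26 ± 0.24, Bhlhe40 0.23 ± 0.17, Arntl 0.18 ± 0.11, Cry2 0.14 ± 0.09, Nr1d1 0.12 ± 0.14, Per1 0.09 ± 0.12, Clock 0.08 ± 0.08, Csnk1e 0.05 ± 0.14, Timeless 0.02 ± 0.11 and Csnk1d 0.01 ± 0.08. Against 0 h, Cry1 was lower at 6 h by −1.28 ± 0.25 and was not called at 24 h, at −0.62 ± 0.25. At 24 h Rora was higher by 1.19 ± 0.24 and Per3 by 1.22 ± 0.37 (adjusted p = 0.0496). Of the clock output genes, Tef rose by 1.31 ± 0.40 at 24 h, and Usp2, Nfil3 and Pnp fell at both times, with Usp2 at −1.98 ± 0.33 at 6 h and −1.70 ± 0.33 at 24 h, and at −1.37 and −1.11 without experiment 1. The clock output list was lower at 6 h with an adjusted p = 0.0461, an adjusted p = 0.0582 with the block and an adjusted p = 0.188 with an estimated correlation. In experiment 1 Tef read 9.49 at 18 h and 11.45 at 30 h, against 11.08 and 9.82 in experiment 2 and 11.02 and 10.40 in experiment 3. Without those 2 arrays of experiment 1 Per3 was called rhythmic (adjusted p = 0.0445 by limma). The 2 arrays were picked on clock genes after the data were seen, so this call is no independent test of a rhythm.

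**Figure D3:**
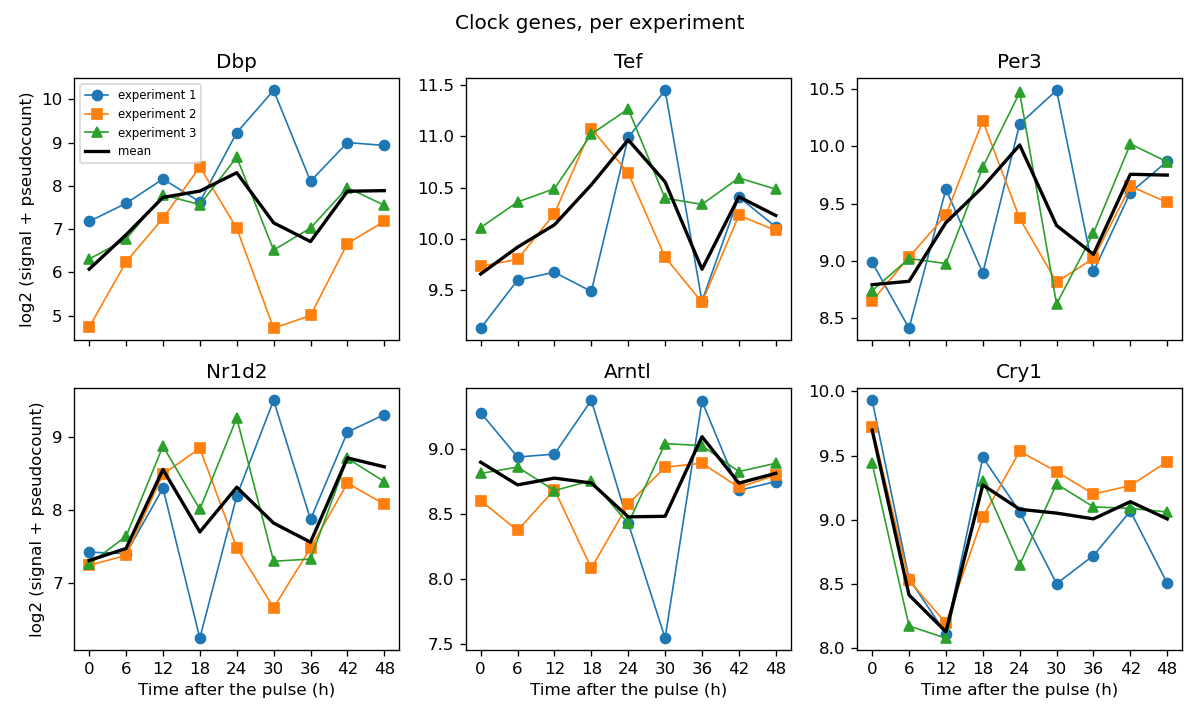
Each panel plots the log2 value of 1 clock or clock output gene (y axis) against time in hours (x axis), with 1 line per experiment and the mean in black. At 30 h experiment 1 lay above the others for Dbp, at 10.21 against 4.71 and 6.52.

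From 6 h to 48 h, 209 probe sets rose and 246 fell along a line, against 600 and 673 with the block, and 143 and 269 with each array centred on its median. The test asks only for a linear term other than 0, so a step within the course can be called too. Dpt, which encodes the matrix protein dermatopontin, rose by 1.77 ± 0.25 per day, Klf4 by 1.14 ± 0.20, Agtr2, an angiotensin receptor gene, by 0.95 ± 0.19, Hk2 by 0.90 ± 0.19 and Ifi202b by 0.88 ± 0.13. Prss23, Dusp1, Atf3, Ccnd1 and Adm rose by between 0.86 and 0.76 per day. Tgfbi fell by 1.34 ± 0.18, Adgrg1 by 1.28 ± 0.35, Tmem176a by 1.23 ± 0.15, Mgst2 by 1.21 ± 0.27 and Bcl3 by 1.07 ± 0.31. Csrp2, Tagln, Ptprn, Tnc and Nmt2 fell by between 1.02 and 0.91 per day.

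Of 35 genes of G2 and mitosis, 2 fell along this line, Smc4 at −0.48 ± 0.11 and Top2a, the topoisomerase of mitotic chromosomes, at −0.30 ± 0.08 per day, against 19 adjusted over the list alone and 22 with the block. Camera gave an adjusted p = 6.30e-08, and an adjusted p = 0.388 with an estimated correlation. The median of this list dropped between 12 h and 18 h, as given above, so its calls do not show a steady fall to 48 h. Of 19 heat shock genes, 6 rose and 1 fell, with Hspa4 at 0.55 ± 0.10, Hsp90aa1 at 0.54 ± 0.13 and Hsph1 at 0.52 ± 0.12 per day and St13 at −0.51 ± 0.10, and the list kept its call with an estimated correlation (adjusted p = 0.0479). Of 24 immediate early genes, 7 rose and 1 fell, with an adjusted p = 4.27e-06, and an adjusted p = 0.0876 with an estimated correlation. Of 35 genes of ribosome biogenesis and MYC targets, 6 rose, 11 adjusted over the list alone and 15 with the block, with Nme1, of which another probe set had the opposite sign, at 0.64 ± 0.17 and Nop56 at 0.59 ± 0.12, with an adjusted p = 3.04e-05, and an adjusted p = 0.131 with an estimated correlation. Of 19 ER chaperone genes, 3 rose, against 7 with the block, among them Hspa5 at 0.58 ± 0.16, with an adjusted p = 0.192 with an estimated correlation. Of 20 genes of fatty acid oxidation, 5 fell, 9 adjusted over the list alone and 10 with the block, with Echs1 at −0.50 ± 0.13 and Acadm at −0.39 ± 0.09, and the list kept its call (adjusted p = 0.00954 with an estimated correlation). Without experiment 3 the trend had 37 calls, without experiment 2 it had 91 and without experiment 1 it had 737.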

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

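The fits without the 18 h and 30 h arrays of experiment 1 were chosen after seeing the data. With the experiment as a replicate block, 1246 probe sets were called at 6 h against 0 h, 1387 at 24 h against 0 h, 42 at 48 h against 24 h, 1968 over time, 1273 along the trend and 65 for a rhythm that differed between cycles, and all calls made without the block were among them. With array weights the same 6 counts were 803, 811, 10, 1134, 720 and 1. Leaving out each experiment in turn gave 110 to 348 at 6 h, 126 to 407 at 24 h, 0 to 5 at 48 h against 24 h, 31 to 504 over time, 37 to 737 along the trend and 0 to 1 between cycles. Each highest count came without experiment 1 and each lowest without experiment 3, at 48 h against 24 h and between cycles also without experiment 2. Each time point then keeps 2 arrays; the cause of the rise to 737 was not tested. Scaling as deposited, median centring and eBayes without the intensity trend each gave 0 at 48 h against 24 h. The trend gave 189 without 6 h, 284 without 12 h, 267 without 30 h, 123 without 36 h, 287 without 48 h and 743 with 0 h included. The difference between cycles gave 1 call without 12 h, without 18 h, without 24 h and without the 2 later-deposited 12 h arrays. Without the 18 h and 30 h arrays of experiment 1, 1 probe set differed at 48 h against 24 h and 1 was rhythmic; with the block as well the counts were 1217, 1362, 47, 1872, 1271 and 37, with 3 rhythmic and 1 list enriched for rhythm. The cause of these shifts was not tested. With an estimated correlation 3 lists were called at 6 h, 0 at 24 h and 2 for the trend. No list reversed. With 0 h included the trend changed sign for Pcna (−0.11), Plin2 (0.0479), Acadm (0.0241) and Hsph1 (−0.22), and the trend of Bhlhe40 ran from −0.503, where it was called, without experiment 1 to 0.338 without experiment 2. The rhythm count was 0 under every setting fixed in advance, periods of 20 h to 28 h included.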

Other observations

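The tests by other splits and permutations of the arrays, those on the 18 h and 30 h arrays of experiment 1 and those on the difference between experiments were chosen after the results they bear on were seen. Some gene groups were measured without standing in a comparison above. Of 24 measured ribosomal protein genes, none passed at 6 h, 2 rose at 24 h, Rpl22 by 0.63 ± 0.17 and Rpl37a by 0.33 ± 0.10, and 2 fell along the trend, Rpl13a at −0.41 ± 0.11 per day and Rpsa at −0.23 ± 0.06. Of 47 genes of oxidative phosphorylation, none passed at 6 h and 3 fell at 24 h, against 9 lower and 1 higher with the block, with Atp5d at −0.77 ± 0.23. Of 30 genes of growth factors and receptors, 4 rose and 1 fell at 24 h, against 11 and 1 with the block, among them Igf2 at 0.89 ± 0.15 and Fgf7 at −0.70 ± 0.20. Cd68, a macrophage marker, fell by 0.51 ± 0.09 per day.

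Other splits of the arrays were set against the counts. For 3 arrays against 3 there are 10 splits, too few for a share under 0.05: the real counts were 453 at 6 h, 519 at 24 h and 2 at 48 h against 24 h, each reached by 1 split, the real one, and the highest of the others were 1, 0 and 1. For the lists at 6 h the real count was 16 and the highest other 11, with 1 split as large. At 24 h it was 11 and the highest other 16, with 3 of 10 as large. The real splits part all 3 same-numbered pairs, as 3 others do. Among those 3 the highest were 0 probe sets in each comparison, 9 lists at 6 h and 16 lists at 24 h. The 6 splits that keep a pair together, and so also set experiments against each other, gave at most 1, 0 and 1 probe sets, 11 lists at 6 h and 12 lists at 24 h. Each split but the real one moves 1 array of each time point to the other. It thereby keeps part of the change over time in the contrast and puts part into the spread. The counts of these splits therefore do not show what chance alone gives. Of 100 permutations of the time labels within experiments, 1, the real one, reached 544 probe sets over time and 1 reached the 455 of the trend, with 0 as the highest of the others, so chance was excluded for these 2 counts. It was not excluded for the 9 lists of the trend, which 9 of 100 permutations reached, with 14 as the highest. The rhythm, the difference between cycles and the lists of rhythmic genes had 0 calls, which all 100 permutations reached, with 1, 0 and 0 as the highest others. Any permutation reaches a count of 0, so for these 3 results the permutations could decide nothing.

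In experiment 1 some clock genes read low at 18 h and high at 30 h, such as Nr1d2 at 6.24 and 9.51, against 8.85 and 6.66 in experiment 2 and 8.01 and 7.30 in experiment 3. Arntl went the other way, at 9.37 and 7.55 against 8.09 and 8.86 and 8.76 and 9.04, and Dbp stood apart at 30 h, at 10.21 against 4.71 and 6.52, but not at 18 h, at 7.63 against 8.44 and 7.57. Without those 2 arrays and with the block, Tef (adjusted p = 0.00309, peak 20.8 h), Per3 (adjusted p = 0.0198, peak 20.2 h) and Dbp (adjusted p = 0.0478, peak 20.0 h) were called rhythmic, and of the 84 pairs of arrays of 1 experiment only 1, this one, gave 3 clock calls when left out, with 0 as the highest of the others. As the pair was chosen on clock genes, its place among the 84 is no independent evidence. Mislabelled samples, an exchange of the 2 arrays, may account for the pattern, though the 2 arrays were chosen on these clock genes. On 500 time-varying probe sets outside the clock lists that exchange ranked 2 of 28. In each experiment 1 to 3 exchanges beat the labelled order, in experiments 2 and 3 only exchanges of neighbouring time points. The exchange of 18 h and 30 h gave a squared distance of 510.3 in experiment 1, against 525.1 as labelled. In experiments 2 and 3 it gave larger distances than the labels, 602.3 against 592.5 and 562.1 against 547.8. In experiment 1 the exchange of 24 h and 30 h came nearer still, at 508.7. These distances go with an exchange of 18 h and 30 h but do not single it out, so it could not be decided. A shifted phase in experiment 1 stays open too: a delay of 6 h gave the highest mean correlation of 6 clock profiles, 0.44 ± 0.47 (SD over genes), against −0.22 ± 0.26 with no delay and 0.84 ± 0.06 after the exchange, on genes picked because they showed the pattern.

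Experiment 1 stood apart from the other 2 over much of the transcriptome, with 3801 probe sets differing from experiment 2 and 3484 from experiment 3, against 2055 between experiments 3 and 2. Overall brightness of the arrays was evened out by quantile normalization before these counts were made, so they cannot show what part it had. At least 3484 probe sets still differed after that step. Effects of brightness on single probe sets were not tested. In these counts, and in the list tests of this paragraph, the arrays of an experiment stood as its replicates, though they are a series from 1 experiment. The p-values behind them therefore do not measure the spread between experiments. RNA quality stays open, because its measures point apart: in the actin ratio experiment 3, at 1.495, was nearer experiment 1 (1.58) than experiment 2 (1.24), while in the Gapdh ratio, at 0.746 against 0.791 and 0.766, it was nearer experiment 2, as on the first principal component, where it lay 3.37 times as far from experiment 1 as from experiment 2. A lower share of dividing cells may contribute and could not be decided: the medians of the G2 and mitosis and S phase lists were −0.58 and −0.25 in experiment 1 relative to the others, with an adjusted p = 0.000512 and 0.0408 by camera and an adjusted p = 0.995 for both with an estimated correlation.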
